A study of Homo sapiens with 24 samples.

How the data were processed

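Total RNA from 24 human surgical specimens had been hybridised to single-colour oligonucleotide arrays with 22283 probe sets each. Per the labels' titles, 8 specimens were normal esophageal epithelium, 8 were Barrett's esophagus and 8 were adenocarcinoma, and the series title calls the adenocarcinomas associated with Barrett's esophagus. The deposited table holds 1 intensity per probe set and array on a linear scale. RNA was extracted by an earlier protocol that the labels cite. The array software and its settings are not given in the sources used here. In the deposited intensities, the mean after dropping the lowest and the highest 2% of probe sets lay between 500.2 and 500.3 on every array, so each array had been scaled to a common trimmed mean before deposit, and the array medians ran from 164.5 to 209. No further normalization between arrays was applied. The table carries no detection calls and no background values, so no gene is called absent, and the number of arrays limits the precision.

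Intensities were turned into log2(intensity + 16), a scale on which the fold change of a dim gene is smaller than the ratio of its intensities. A probe set was tested if its intensity was above the 40th percentile of its array on at least 8 arrays. Gene names came from an annotation table of the array, with older symbols updated through a RefSeq gene table of the GRCh38.p14 assembly, used for names only. Of the probe sets, 19071 had 1 gene symbol, 1043 had several and 2169 were unnamed here, and the last 2 kinds were not used. Of the 14677 probe sets past the filter, the brightest one per gene was kept, which left 8932 genes. Each gene was fitted over all 24 arrays with 1 mean per class by limma 3.58.1 (lmFit, contrasts and eBayes) in R 4.3.3. The 3 comparisons were Barrett's minus normal, adenocarcinoma minus normal and adenocarcinoma minus Barrett's, each two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Differences are given with limma's standard error (SE) and, where stated, with the number of arrays of the first class that lie beyond the median of the second.

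Before the data were examined, 32 gene lists were fixed. They cover squamous differentiation (epidermal differentiation complex, squamous keratins, cornified envelope, desmosome, kallikreins and serpins, basal layer), columnar epithelium (intestinal, gastric, simple epithelial, transcription factors, enteroendocrine), secretion, mitosis, DNA replication, matrix and its proteases, cell types (endothelial, smooth muscle, T and NK, B and plasma, monocyte and macrophage, mast, erythrocyte), interferon, chemokines, metabolism (retinoid, xenobiotic, hypoxia and glycolysis, oxidative phosphorylation), genes recurrently amplified in esophageal adenocarcinoma, Wnt targets and ribosomal proteins. The 31 lists with at least 5 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data. A further planned test, limma's fry, asks whether the members of a list changed in a common direction, without comparison with other genes. It had the same adjustment over the lists. The erythrocyte list had 3 tested members and no list test. A list score of an array is the mean over tested members of the log2 deviation from the mean of the 24 arrays. Genes were named by a rule fixed at the same time. It took the 8 largest increases and the 8 largest decreases among genes that passed in a comparison, and up to 4 members of each list with the smallest p. Genes named outside it are said to be. Probe sets with the suffix _s_at or _x_at can cross-hybridise, and values of close relatives (the SPRR genes, SERPINB3 and SERPINB4, KRT8 and KRT18 with their pseudogenes, immunoglobulin genes) are uncertain for that reason.

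Array quality was compared between classes by exact permutation tests, two-sided, of 4 measures in 3 comparisons, with Benjamini-Hochberg adjustment over the 12 tests. The measures were the 3' over 5' log2 ratio of the ACTB and of the GAPDH control probe sets, the median intensity, and the share of the summed intensity in the 100 brightest probe sets. Permutation tests and plots used Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The labels number the specimens 1 to 8 in each class without saying what a number stands for, so no block entered the fit.

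The fit was tested on simulated data drawn with each gene's mean and residual SD from the real arrays and independent between genes. Among 8932 genes, 50 drawn at random were changed at each of 4 sizes. The members of 1 gene list were also shifted by 1 on the log2 scale in each run. At a change of 1 on the log2 scale, 48% of the changed genes passed for Barrett's minus normal, 60% for adenocarcinoma minus normal and 50% for adenocarcinoma minus Barrett's. At a change of 2, the shares were 90%, 92% and 92%. These shares need not hold for correlated genes or for genes with a larger spread. KRT14 and KRT4 differed by more than that between adenocarcinoma and Barrett's esophagus and did not pass. Of the 183, 192 and 203 genes that passed in these simulations, 15, 13 and 21 had not been changed. Alternatives fixed beforehand were a pseudocount of 1, a floor of 64, quantile normalization, a shift of each array to a common median, no filter, a 60th percentile filter, the median of a gene's probe sets, all probe sets, probe sets without the suffix _x_at or _s_at, the sample number as a fixed or random block, array weights, only the classes compared, a robust variance trend, a rank test, and leaving out each array. Leaving out the arrays that stood apart, 2 or 3 together, and adding the 3' over 5' ratio as a covariate were chosen after seeing the data.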

Results

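The 24 arrays compared 3 tissue classes of the human esophagus, with 8 specimens each. Normal esophageal epithelium is a stratified squamous lining. In Barrett's esophagus a columnar epithelium with intestinal features takes its place, and the series title calls its adenocarcinomas associated with Barrett's esophagus. The comparisons ask which transcripts distinguish the 3 classes. The 100 brightest probe sets held between 10.5% and 20.9% of the summed intensity of an array. Over the tested genes, the median SD of log2 intensity within a class was 0.55 in normal epithelium, 0.44 in Barrett's esophagus and 0.53 in adenocarcinoma (n = 8 each). The labels do not say whether the specimens of a class came from separate donors, so the p-values measure the spread between these specimens.

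Squamous and columnar transcripts separated most arrays. Keratin 13 (KRT13), a keratin of the upper layers of squamous mucosa, had an intensity of 27767 to 50661 on 7 of the 8 normal arrays and of 9268 to 53108 on all 8 Barrett's arrays. On 6 adenocarcinoma arrays it lay between 99.3 and 998.3. The trefoil peptide TFF1, secreted with gastric mucus, lay between 63.9 and 204 on 7 normal arrays, between 429 and 31566 on the Barrett's arrays and between 3076 and 20194 on the adenocarcinoma arrays.

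**Figure D1:**
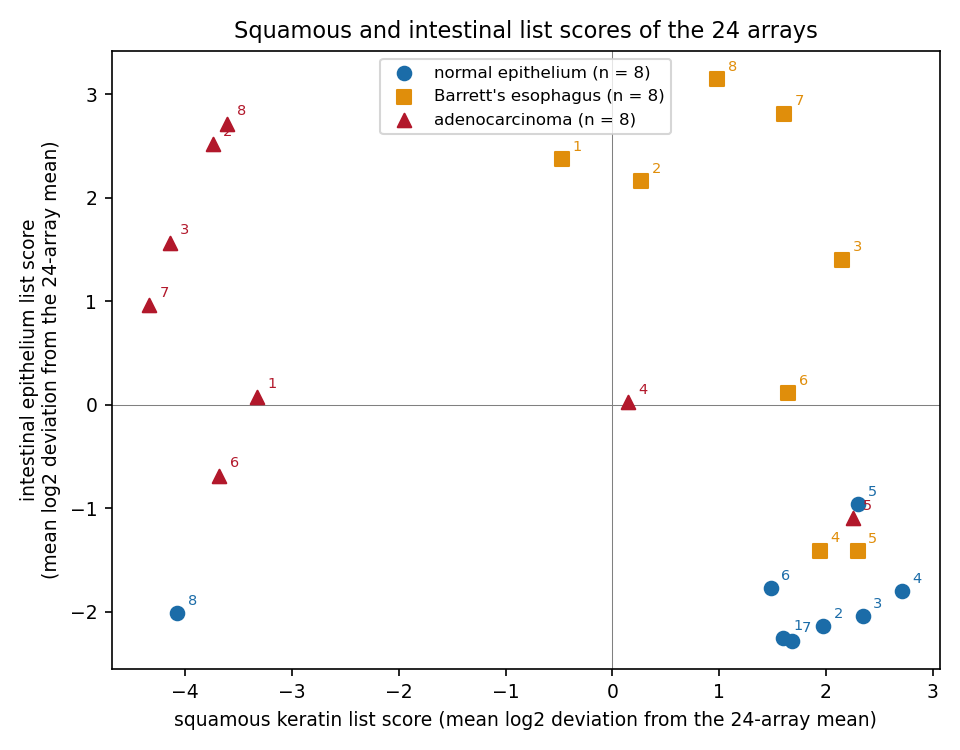
Score of the squamous keratin list (x axis) against the score of the intestinal epithelium list (y axis) for each of the 24 arrays, both as the mean log2 deviation from the mean of all arrays, with the sample number beside each point. Normal array 8 (-4.07 on the x axis) lies with the adenocarcinoma arrays for squamous keratins, and adenocarcinoma array 5 (2.25) lies beside normal array 5 (2.30).

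Several arrays stood apart from their class. Normal array 8 had a mean correlation of 0.602 with the other normal arrays, and its KRT13 intensity was 195. Its score for the smooth muscle list, which holds desmin (DES) and other contractile proteins, was 3.29, the highest of the normal arrays, with a DES intensity of 18901 against 586 to 6217 on the other normal arrays. Normal array 5 and adenocarcinoma array 5 were the most alike of all 276 pairs of arrays (r = 0.972 across genes, which are not independent replicates). Adenocarcinoma array 5 carried squamous transcripts at normal level (KRT13 36735). Normal array 5 carried columnar and matrix transcripts, with TFF1 at 9532 and the collagenase MMP1 at 4235, against 7755 and 3863 on adenocarcinoma array 5. Adenocarcinoma array 4 also held squamous transcripts (KRT13 15105), and Barrett's arrays 4 and 5 had low scores for the intestinal list (-1.41 and -1.41) against 0.114 to 3.15 on the other Barrett's arrays.

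Array quality differed between normal epithelium and both other classes. The 3' over 5' log2 ratio of the ACTB control, which rises as RNA is degraded, was 0.247 ± 0.102 (SD, n = 8) in normal epithelium, 0.469 ± 0.131 in Barrett's esophagus and 1.13 ± 0.899 in adenocarcinoma. It was higher than in normal epithelium in Barrett's esophagus (exact permutation test, adjusted p = 0.0280) and in adenocarcinoma (exact permutation test, adjusted p = 0.0373). Adenocarcinoma arrays 2 and 7 had the highest values, 2.64 and 2.19. Between adenocarcinoma and Barrett's esophagus the ACTB ratio did not pass (exact permutation test, adjusted p = 0.0979). The GAPDH ratio gave adjusted p = 0.0496, 0.0373 and 0.101 in these 3 comparisons by the same test. The median intensity of an array was 188.5 on average in adenocarcinoma and 176.7 in normal epithelium (exact permutation test, adjusted p = 0.0410).

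**Figure D2:**
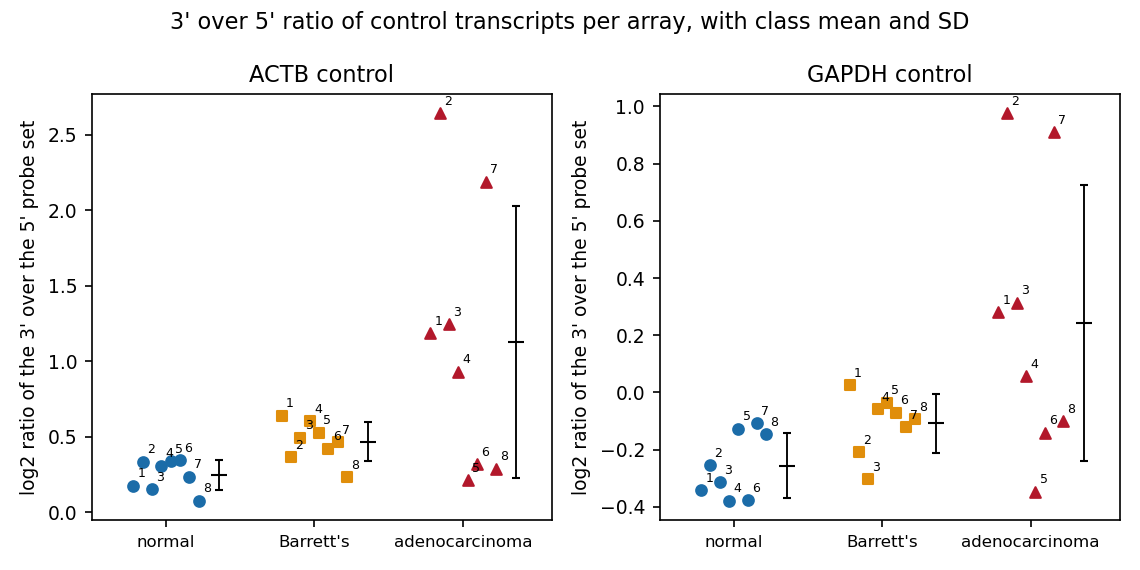
The 3' over 5' log2 ratio of the ACTB control (left) and the GAPDH control (right) on each array, by class, with the sample number beside each point and the class mean and SD as a black bar (n = 8). The ACTB mean is 0.247 in normal epithelium, 0.469 in Barrett's esophagus and 1.13 in adenocarcinoma.

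In Barrett's esophagus, compared with normal epithelium, transcripts of gastric and intestinal columnar epithelium rose by the largest factors. The gastric mucin MUC5AC (probe set 214385_s_at) was higher by 6.31 ± 1.10 on the log2 scale (SE, n = 8 and 8), or 79.4-fold (adjusted p = 0.00199, 8 of 8 Barrett's arrays above the normal median). TFF1 (205009_at) rose 45.0-fold and TFF2 (214476_at) 40.5-fold, the disulfide isomerase AGR2 (209173_at) 34.3-fold, annexin ANXA10 32.0-fold, the tetraspanin TSPAN8 30.0-fold and the galectin LGALS4 26.8-fold, each on 8 of 8 arrays. Of 8932 genes, 208 rose and 38 fell by limma, and 189 and 17 of these by 2-fold or more. The balance depended on normal array 8, with 349 higher and 199 lower without it, and 424 higher and 332 lower without it and adenocarcinoma array 5 (335 and 158 by 2-fold or more). With array weights 725 were higher and 472 lower. On all arrays the decreases were smaller than the increases, and the largest was that of FCER1A, the alpha chain of the IgE receptor of mast cells, at -1.69 ± 0.40 (adjusted p = 0.0201). It was followed by the antisense RNA ACVR2B-AS1, VAT1, the growth factor GDF7, LDOC1, GNG4, PIR and the phosphomannomutase PMM1, whose differences ran from -1.46 to -1.28. ACVR2B-AS1, LDOC1 and PMM1 passed without any 1 array. FCER1A was lost without normal array 1 or 3 or Barrett's array 1, GDF7 without normal array 2 or Barrett's array 8, VAT1 without normal array 1, 2, 3 or 4 or Barrett's array 1, 2 or 8, PIR without normal array 1, 3 or 6 or Barrett's array 1, 2 or 6, and GNG4 without any 1 of 12 arrays (normal 1, 2, 3, 4, 6 and 7, Barrett's 1, 2, 4, 5, 7 and 8). The largest decreases without normal array 8 and adenocarcinoma array 5 were those of CRISP3 (-3.17), SLURP1 (-3.11), KRT1 (-2.81) and the squamous protein FLG (-2.45), with FCER1A at -1.94. OLFM4 rose 28.0-fold on 6 of 8 arrays and was lost without normal array 1, 2, 3, 4 or 7 or Barrett's array 1, 2, 6, 7 or 8.

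Of 24 tested intestinal genes, 12 rose and none fell over all genes, and 23 rose adjusted over the list alone. Their median difference was 3.12 (camera adjusted p = 1.29e-19, adjusted p = 0.0798 with an estimated correlation). The brush border peptidases DPP4 (2.09 ± 0.37) and ANPEP (4.64 ± 0.96) and the surface antigen GPA33 (3.43 ± 0.70) rose on 8 of 8 arrays. Of 14 gastric genes, 8 rose over all genes and 11 adjusted over the list alone, with a median of 3.73 (camera adjusted p = 2.37e-14, adjusted p = 0.0576 with an estimated correlation). The aspartic protease CTSE rose by 4.27 ± 0.74. Of 16 simple epithelial keratin and tight junction genes, 5 rose over all genes, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.49e-07, adjusted p = 0.181 with an estimated correlation). They included KRT8 (2.66 ± 0.52), EPCAM (3.26 ± 0.66) and KRT18 (1.92 ± 0.45). Among 11 columnar transcription factors, GATA6 (2.47 ± 0.53) and FOXA2 (2.55 ± 0.58) rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.000485, adjusted p = 0.181 with an estimated correlation). Of 20 genes of the unfolded protein response and secretion, 2 rose over all genes and 9 adjusted over the list alone, with the membrane-bound transcription factor CREB3L1 at 3.41 ± 0.51 (camera adjusted p = 1.04e-06, adjusted p = 0.0576 with an estimated correlation). Normal array 5 held the highest gastric score of the normal arrays, 0.722 against a class mean of -2.18.

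Some transcripts of inflammation and of matrix proteases were higher, unevenly between the Barrett's arrays. Barrett's arrays 4 and 5, which had low intestinal scores, had chemokine scores of 1.62 and 1.77, against -0.345 to 0.285 on the other 6 and -1.09 to 0.382 on the normal arrays. They also had the highest protease (1.13 and 1.20) and collagen scores (0.974 and 1.39) of the class, and the highest endothelial (1.33 and 1.31) and monocyte and macrophage scores (0.549 and 0.802). CXCL1 had an intensity of 8618 and 8872 on these arrays and of 272.4 to 1374 on the other 6, while IL1B lay between 556.6 and 3065 on the other 6 and between 233 and 473 on the normal arrays. Of 24 chemokine, cytokine and prostaglandin genes, 4 rose over all genes and 8 adjusted over the list alone, among them IL1B (2.15 ± 0.38) and CXCL1 (3.02 ± 0.70) (camera adjusted p = 2.45e-06, adjusted p = 0.181 with an estimated correlation). Of 26 interferon response genes, 4 rose over all genes and 6 adjusted over the list alone, with OASL at 1.92 ± 0.41 and IFI27 at 1.72 ± 0.38 (camera adjusted p = 4.49e-07, adjusted p = 0.341 with an estimated correlation). Of 21 matrix proteases and regulators, 2 rose over all genes, the urokinase receptor PLAUR (3.99-fold) and MMP1 (4.24 ± 1.10), and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000485, adjusted p = 0.240 with an estimated correlation). The MMP1 call was lost without any 1 of 10 arrays, normal arrays 1, 2, 3, 4, 6 and 7 and Barrett's arrays 1, 4, 5 and 8. The endothelial gene PLVAP rose by 1.65 ± 0.36, the 1 of 15 endothelial genes to pass over all genes, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000628, adjusted p = 0.408 with an estimated correlation). None of 26 collagen and fibroblast genes passed over all genes or over the list alone, and their median was 0.84 (camera adjusted p = 0.00103, adjusted p = 0.677 with an estimated correlation).

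In the main squamous differentiation lists, no difference between Barrett's esophagus and normal epithelium was detected on all arrays. The spread of the normal class was wide. Its squamous keratin scores had an SD of 2.19, with normal array 8 at -4.07, against an SD of 0.974 in Barrett's esophagus. How much squamous tissue the Barrett's specimens held was not measured, so these values do not describe the columnar epithelium alone. None of 14 epidermal differentiation complex genes, 9 squamous keratins, 17 cornified envelope genes or 15 kallikreins and serpins passed, over all genes or over the list alone. The medians of these lists were 0.08, 0.22, -0.47 and 0.03 (camera adjusted p = 0.962, 0.663, 0.222 and 0.972). Without normal array 8 and adenocarcinoma array 5, the medians were -0.81, -0.48, -1.18 and -0.70, and 1, 2, 5 and 0 members fell over all genes. In the basal layer list, the integrin ITGA6 (1.97 ± 0.40) and the laminin LAMB3 (1.60 ± 0.38) rose, 2 of 14 genes over all genes and 3 adjusted over the list alone (camera adjusted p = 0.429). The desmosomal PKP2 rose by 1.80 ± 0.41, 1 of 11 desmosome genes, and 2 rose adjusted over the list alone (camera adjusted p = 0.737).

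Of 33 mitosis genes none passed over all genes or over the list alone, and their median was 0.48 (camera adjusted p = 6.92e-05, adjusted p = 0.656 with an estimated correlation). Without normal array 8 and adenocarcinoma array 5 this median was 0.23 (camera adjusted p = 0.0574). None of 27 DNA replication genes passed either (median 0.02, camera adjusted p = 0.854). Of 19 genes recurrently amplified in the adenocarcinoma, 3 rose over all genes, MET (2.39 ± 0.43) and TSPAN1 (4.56 ± 0.83) among them, and 4 adjusted over the list alone (camera adjusted p = 0.0407, adjusted p = 0.341 with an estimated correlation). Of 12 B and plasma cell genes, none passed over all genes and 2 rose adjusted over the list alone (camera adjusted p = 0.000463, adjusted p = 0.341 with an estimated correlation). FCER1A was the 1 of 8 mast cell genes that fell, over all genes and over the list alone (camera adjusted p = 0.0332, adjusted p = 0.341 with an estimated correlation). The medians of 35 oxidative phosphorylation and 31 ribosomal protein genes were -0.16 and -0.19 with no member past the test (camera adjusted p = 0.00275 and 0.0015, adjusted p = 0.341 and 0.711 with an estimated correlation).

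For the other lists, camera detected no difference from the remaining genes between Barrett's esophagus and normal epithelium. Smooth muscle genes had a median of -0.69 (camera adjusted p = 0.0558), and T and NK cell (0.04), monocyte and macrophage (0.06) and enteroendocrine genes (0.04) each had a camera adjusted p of 0.663, with no member past the test. The 3 erythrocyte genes had a median of -0.31 and did not pass. RARA rose by 1.07 ± 0.25 among 23 retinoid and aldehyde metabolism genes, the 1 to pass over all genes and over the list alone (camera adjusted p = 0.856). The sulfotransferase SULT1A1 (1.69 ± 0.36) was 1 of 2 xenobiotic metabolism genes out of 22 to rise over all genes, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.273). Of 21 hypoxia and glycolysis genes none passed over all genes, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.429). OLFM4 was the 1 of 11 Wnt target and stem cell genes to rise over all genes, and 2 rose adjusted over the list alone (camera adjusted p = 0.407). The median and the camera direction, which is relative to the other genes, differed in sign for several lists without a camera call. The median was above 0 and the direction down for the epidermal differentiation complex (mean 0.04), squamous keratins (0.05), kallikreins (0.06) and DNA replication (0.02). The median was below 0 and the direction up for the desmosome (mean 0.06), basal layer (0.18) and Wnt lists (0.62), and the retinoid list had a median of -0.16 with a mean of 0.01.

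The count of 246 genes was 155, 157 and 157 without normal array 1, 2 or 3, 143 and 150 without Barrett's array 1 or 8, 548 without normal array 8, and 756 without normal array 8 and adenocarcinoma array 5. It was 134 when probe sets with the suffix _x_at or _s_at were left out and 1197 with array weights.

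**Figure D3:**
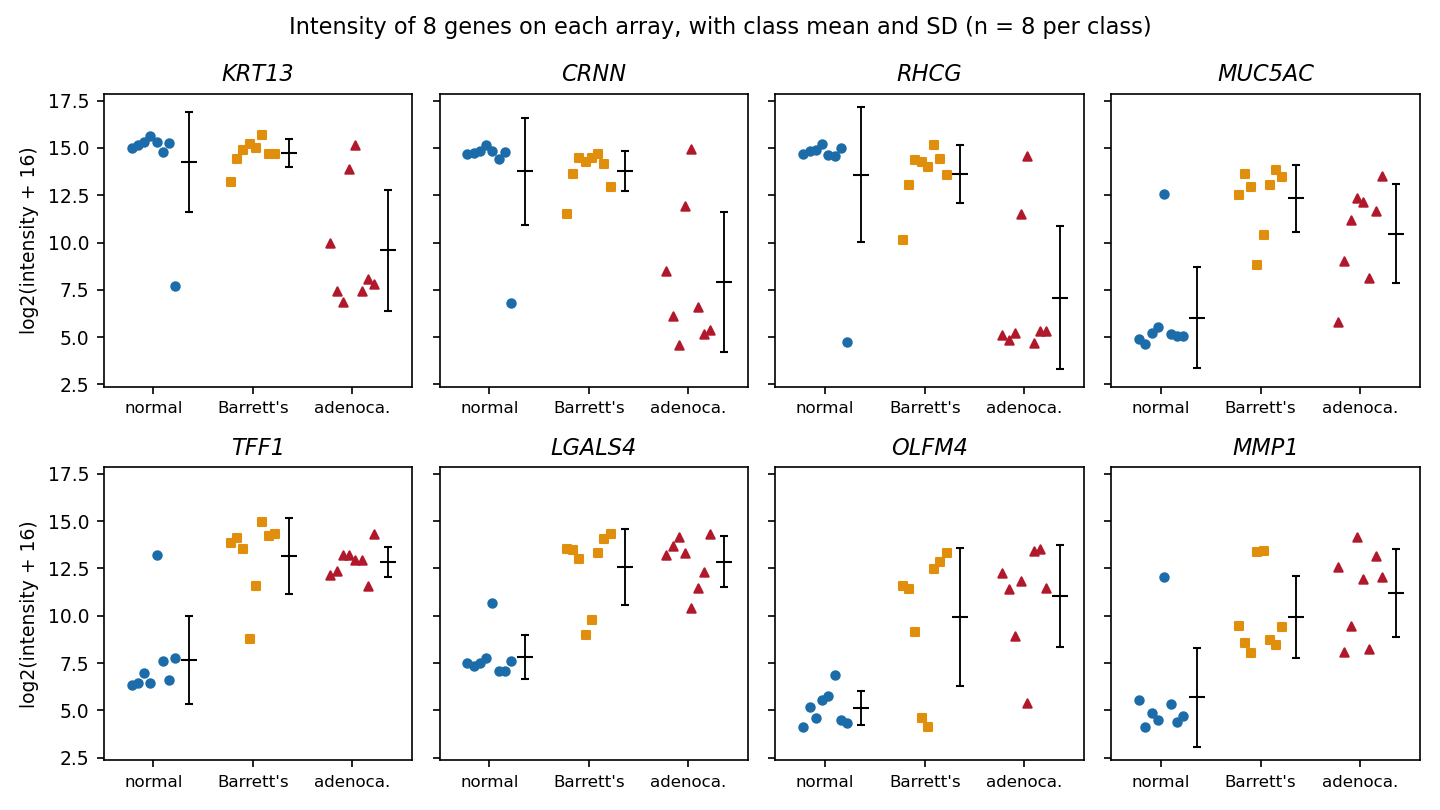
Log2(intensity + 16) of 8 genes on each array of the 3 classes (normal, Barrett's, adenocarcinoma written as adenoca.), with the class mean and SD as a black bar (n = 8). KRT13, CRNN and RHCG fall in adenocarcinoma, with normal array 8 low and adenocarcinoma array 5 high, and MUC5AC, TFF1, LGALS4, OLFM4 and MMP1 are higher in Barrett's esophagus and adenocarcinoma, with normal array 5 high for 4 of these 5 genes.

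In adenocarcinoma, compared with normal epithelium, the class means of squamous differentiation transcripts were lower and those of columnar, matrix and cell division transcripts were higher. Adenocarcinoma arrays 4 and 5 carried squamous transcripts and normal array 8 had low levels of them. How much squamous tissue each specimen held was not measured. The ammonium transporter RHCG (219554_at) fell by 6.50 ± 1.45 on the log2 scale (SE, n = 8 and 8), a 90.5-fold decrease (adjusted p = 0.00327), and the difference of cornulin (CRNN, probe set 220090_at) was -5.86 ± 1.28. The other largest decreases, SPRR2B, KRT15, CRCT1, the desmosomal PKP1, SLURP1 and the transglutaminase TGM1, were between 57.2-fold and 39.9-fold, on 7 or 8 of 8 arrays. The crypt marker OLFM4 (212768_s_at) rose 60.2-fold, AGR2 52.7-fold, TSPAN8 50.5-fold, the trypsin inhibitor SPINK1 48.1-fold, MMP1 45.6-fold, TFF1 36.1-fold, LGALS4 33.0-fold and the Golgi protein GOLM1 29.8-fold, each on 8 of 8 arrays. By limma 1235 genes rose and 849 fell, and 759 and 480 of these by 2-fold or more. With each array shifted to a common median, 970 rose and 1090 fell.

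Of the epidermal differentiation complex, which encodes cornified envelope proteins on the surface of squamous cells, 13 of 14 genes fell over all genes and 14 adjusted over the list alone, with a median of -4.19 (camera adjusted p = 3.13e-09, adjusted p = 0.267 with an estimated correlation). All 9 squamous keratins fell, over all genes and over the list alone, with KRT4 at -5.29 ± 1.17 and KRT13 at -4.68 ± 1.13 (camera adjusted p = 1.46e-06, adjusted p = 0.267 with an estimated correlation). Of 17 cornified envelope genes, 15 fell over all genes and 16 adjusted over the list alone, among them the raft protein MAL (-4.97 ± 0.88) and the transglutaminase TGM3 (-5.30 ± 1.09) (camera adjusted p = 1.35e-10, adjusted p = 0.267 with an estimated correlation). Of 15 kallikreins and squamous serpins, 7 fell over all genes and 10 adjusted over the list alone, with KLK13 at -4.07 ± 0.97 (camera adjusted p = 2.94e-06, adjusted p = 0.318 with an estimated correlation). Of 11 desmosome genes, 5 fell and 2 rose over all genes, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.388 with an estimated correlation). DSG1 fell by 3.11 ± 0.84 while DSG2, the desmoglein of simple epithelia, rose by 2.48 ± 0.57. The basal layer list went both ways, with 3 of 14 genes higher, LAMB3, ITGB4 and ITGA6, and 4 lower, among them NOTCH3 (3 and 5 adjusted over the list alone, camera adjusted p = 0.551). Without normal array 8 and adenocarcinoma array 5, the epidermal differentiation complex median was -5.62, that of the squamous keratins -6.41, and RHCG was at -8.83.

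Apart from the enteroendocrine list, the columnar lists were higher. Of 24 intestinal genes, 13 rose over all genes and 15 adjusted over the list alone, with EPS8L3 at 2.62 ± 0.49 (camera adjusted p = 1.71e-07, adjusted p = 0.296 with an estimated correlation). Of 14 gastric genes, 8 rose over all genes and 9 adjusted over the list alone, with CTSE at 4.64 ± 0.74 (camera adjusted p = 1.19e-05, adjusted p = 0.267 with an estimated correlation). Of 16 simple epithelial genes, 8 rose and 1 fell over all genes, and 9 rose and 1 fell adjusted over the list alone, with EPCAM at 4.20 ± 0.66 (camera adjusted p = 0.00386, adjusted p = 0.366 with an estimated correlation). Of 11 columnar transcription factors, 5 rose over all genes, and 5 rose and 1 fell adjusted over the list alone, with FOXA2 at 3.61 ± 0.58, GATA6 at 3.29 ± 0.53 and SOX9 at 2.33 ± 0.54 (camera adjusted p = 0.0220, adjusted p = 0.323 with an estimated correlation). The endoplasmic reticulum chaperones HSPA5 (0.97 ± 0.19) and HSP90B1 (2.11 ± 0.49) rose with 9 of 20 genes of the unfolded protein response over all genes and 15 adjusted over the list alone (camera adjusted p = 1.14e-05, adjusted p = 0.256 with an estimated correlation).

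Cell division transcripts rose, although with the 3' over 5' ratio as a covariate no single gene passed and only the lists did, at the preset correlation. Of 33 mitosis genes, 20 rose over all genes and 28 adjusted over the list alone, among them the kinases AURKA (1.80 ± 0.37), TTK (1.58 ± 0.36) and BUB1 (1.23 ± 0.29) and the kinetochore protein NDC80 (1.67 ± 0.36) (camera adjusted p = 9.69e-09, adjusted p = 0.318 with an estimated correlation). Normal array 8 had the lowest mitosis score, -2.49 against a class mean of -0.499. Of 27 DNA replication genes, 10 rose over all genes, and 13 rose and 1 fell adjusted over the list alone, with the helicase subunits MCM6 (1.05 ± 0.28) and MCM7 (1.12 ± 0.28) (camera adjusted p = 0.000576, adjusted p = 0.323 with an estimated correlation). In order of the mean 3' over 5' log2 ratio, adenocarcinoma arrays 5, 6, 8, 4, 1, 3, 7 and 2 had ratios of -0.0666, 0.0892, 0.0947, 0.494, 0.733, 0.780, 1.55 and 1.81. Their mitosis scores in this order were -0.186, -0.169, 0.505, 0.729, 0.983, 0.452, 0.691 and 1.20. With the ratio as a covariate, chosen after seeing the data, the mitosis median went from 1.09 to 0.62 and the DNA replication median from 0.62 to 0.43. No member of either list then passed over all genes or over the list alone (camera adjusted p = 1.22e-05 and 0.0367, adjusted p = 0.462 and 0.489 with an estimated correlation).

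Of 26 collagen and fibroblast genes, 15 rose over all genes and 15 adjusted over the list alone, with VCAN at 2.45 ± 0.58, COL5A2 at 2.27 ± 0.54 and COL4A1 at 2.02 ± 0.54 (camera adjusted p = 2.61e-05, adjusted p = 0.388 with an estimated correlation). Of 21 matrix proteases and regulators, 9 rose over all genes, and 13 rose and 1 fell adjusted over the list alone, with TIMP1 at 2.40 ± 0.47 and the collagen chaperone SERPINH1 at 3.49 ± 0.76 (camera adjusted p = 0.00046, adjusted p = 0.267 with an estimated correlation). Of 26 interferon response genes, 13 rose over all genes and 16 adjusted over the list alone, with the immunoproteasome subunit PSMB9 at 2.02 ± 0.35 and the tryptophan dioxygenase IDO1 at 2.65 ± 0.53 (camera adjusted p = 1.70e-06, adjusted p = 0.318 with an estimated correlation). Of 24 chemokine and cytokine genes, 10 rose and 3 fell over all genes, and 10 and 4 adjusted over the list alone, with CCL20 at 3.88 ± 0.90 and LIF at 1.86 ± 0.39 (camera adjusted p = 0.0207, adjusted p = 0.388 with an estimated correlation). Among genes recurrently amplified in this tumour, 7 of 19 rose over all genes and over the list alone, led by the receptor MET (3.20 ± 0.43) (camera adjusted p = 0.0155, adjusted p = 0.296 with an estimated correlation). Of 23 genes of retinoid, alcohol and aldehyde metabolism, 8 fell and 3 rose over all genes, and 9 and 4 adjusted over the list alone, with ALDH3B2 at -3.76 ± 0.85 and RARA at 1.21 ± 0.25 (camera adjusted p = 0.0142, adjusted p = 0.267 with an estimated correlation).

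Some immune and stromal cell markers differed as well. Of 12 B and plasma cell genes, 5 rose over all genes and 8 adjusted over the list alone, with a median of 1.23 and the immunoglobulin heavy chain IGHM at 3.57 ± 0.78 (camera adjusted p = 0.0122, adjusted p = 0.388 with an estimated correlation). Of 18 monocyte and macrophage genes, 4 rose over all genes and over the list alone, with AIF1 at 2.37 ± 0.53 (camera adjusted p = 0.0142, adjusted p = 0.441 with an estimated correlation). FCER1A (-2.49 ± 0.40) was 1 of 2 mast cell genes out of 8 to fall, over all genes and over the list alone (camera adjusted p = 0.0236, adjusted p = 0.318 with an estimated correlation). Of 14 T and NK cell genes 3 rose over all genes and over the list alone (camera adjusted p = 0.0664). Of 15 endothelial genes 5 rose and 1 fell over all genes, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.180). None of 14 smooth muscle genes passed over all genes or over the list alone, and their median was -0.75 (camera adjusted p = 0.0385, adjusted p = 0.642 with an estimated correlation). No erythrocyte (mean difference -0.05) or enteroendocrine gene passed (camera adjusted p = 0.636 for the latter).

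Among metabolic lists, 6 of 35 oxidative phosphorylation genes fell over all genes and over the list alone, with ATP5F1A at -0.85 ± 0.19 (camera adjusted p = 7.82e-05, adjusted p = 0.267 with an estimated correlation). Of 21 hypoxia and glycolysis genes 3 rose, VEGFA (1.55 ± 0.31) among them, and 4 fell, BNIP3 (-2.84 ± 0.55) among them, over all genes and over the list alone (camera adjusted p = 0.0324, adjusted p = 0.388 with an estimated correlation). Of 22 xenobiotic metabolism genes 4 rose and 4 fell over all genes, and 6 and 6 adjusted over the list alone, with the receptor AHR at 2.61 ± 0.51 and the peroxidase GPX3 at -2.60 ± 0.48 (camera adjusted p = 0.381). Of 31 ribosomal protein genes RPL10A alone fell (camera adjusted p = 0.0187, adjusted p = 0.649 with an estimated correlation). OLFM4 and SOX4 (1.17 ± 0.30) were among 3 of 11 Wnt target and stem cell genes to rise, and 1 fell, over all genes and over the list alone (camera adjusted p = 0.751).

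With the mean 3' over 5' ratio of both controls as a covariate, chosen after seeing the data, 73 genes rose and 7 fell in adenocarcinoma against normal epithelium. Without it, 1235 rose and 849 fell, and the counts above for matrix, interferon, chemokine and immune lists come from that fit. TFF1, CTSE, CREB3L1 and MET were among those that passed, and none of the 40 genes of the epidermal differentiation complex, squamous keratin and cornified envelope lists did. Without normal array 8 and adenocarcinoma array 5, 3202 genes passed.

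**Figure D4:**
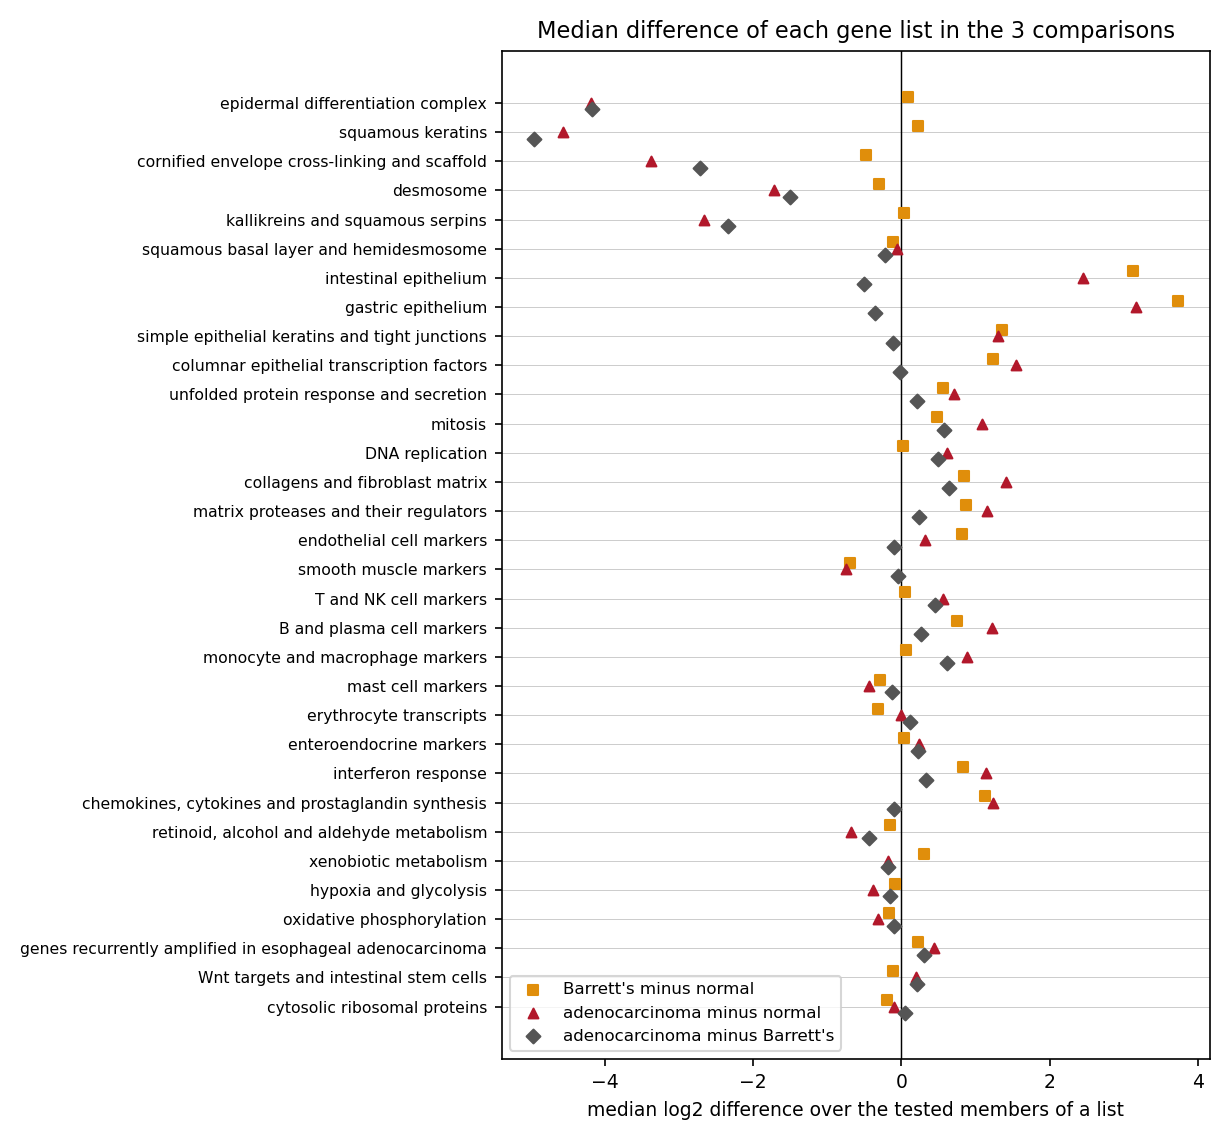
Median log2 difference over the tested members of each gene list (x axis) in the 3 comparisons, marked by square (Barrett's minus normal), triangle (adenocarcinoma minus normal) and diamond (adenocarcinoma minus Barrett's). Squamous keratins lie at 0.22 in Barrett's minus normal and at -4.57 and -4.96 in the comparisons of adenocarcinoma with normal epithelium and with Barrett's esophagus.

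Between adenocarcinoma and Barrett's esophagus no single gene passed over all genes. The largest list medians were those of squamous differentiation lists, which camera called at the preset correlation but not with an estimated one. How much squamous tissue the specimens of either class held was not measured, so a difference in tissue content cannot be told apart from a change in the columnar or tumour cells. By limma, 0 of 8932 genes passed, 1154 had an unadjusted p under 0.05, and the rank test also gave 0. With the 3' over 5' ratio as a covariate, chosen after seeing the data, 0 passed and 362 had an unadjusted limma p under 0.05. Unchanged genes alone could give that many. The sample number as a fixed block gave 2 genes higher and 9 lower. Adjusted over the list alone, 14 of 14 epidermal differentiation complex genes, 7 of 9 squamous keratins, 15 of 17 cornified envelope genes, 13 of 15 kallikreins and serpins and 5 of 11 desmosome genes were lower in adenocarcinoma. Their medians were -4.17, -4.96, -2.72, -2.34 and -1.50 (camera adjusted p = 3.52e-21, 1.86e-12, 2.19e-20, 1.01e-13 and 1.65e-06). With a correlation estimated from the data (0.846, 0.732, 0.821, 0.767 and 0.538), these lists had camera adjusted p = 0.0861, 0.0861, 0.0948, 0.128 and 0.192. Members so closely correlated are not separate evidence. KRT14 was at -6.32 ± 1.39, KRT4 at -5.82 ± 1.17, the antimicrobial S100A7 at -5.71 ± 1.19 and MAL at -4.38 ± 0.88, each with an adjusted p of 0.0861 over all genes.

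Intestinal, gastric, simple epithelial and transcription factor lists had no member past the test over all genes or over the list alone, with medians of -0.51, -0.36, -0.11 and -0.02 (camera adjusted p = 0.0748, 0.0748, 0.398 and 0.936). Of 27 DNA replication genes, 7 were higher in adenocarcinoma adjusted over the list alone, among them RFC4 (0.65 ± 0.15) and MCM3 (0.68 ± 0.18) (camera adjusted p = 4.43e-09, adjusted p = 0.128 with an estimated correlation). The 33 mitosis genes had a median of 0.57 and no member past the test over the list alone (camera adjusted p = 5.37e-07, adjusted p = 0.519 with an estimated correlation). COL10A1, a collagen, was at 2.21 ± 0.50 and the stromal protease MMP11 was 3.99-fold higher, the 1 member each of the collagen and protease lists to pass adjusted over the list alone (camera adjusted p = 0.00357 and 0.0917, adjusted p = 0.627 and 0.584 with an estimated correlation). Of 23 retinoid and aldehyde metabolism genes, none passed over the list alone, and their median was -0.43 (camera adjusted p = 0.000149, adjusted p = 0.0755 with an estimated correlation).

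For the remaining lists too, no member passed over all genes. Of 18 monocyte and macrophage genes 1 was higher adjusted over the list alone (median 0.61, camera adjusted p = 0.0011, adjusted p = 0.519 with an estimated correlation), and of 14 T and NK cell genes none (median 0.45, camera adjusted p = 0.0404, adjusted p = 0.535 with an estimated correlation). Xenobiotic metabolism had 2 of 22 genes lower adjusted over the list alone (camera adjusted p = 0.00438, adjusted p = 0.192 with an estimated correlation). The basal layer (median -0.22), hypoxia (-0.16) and oxidative phosphorylation lists (-0.10) had no member past the test over the list alone, with camera adjusted p = 0.0396, 0.0346 and 0.00438. With an estimated correlation these 3 lists had adjusted p = 0.246, 0.519 and 0.408. Interferon response genes had 2 members higher and chemokine genes 2 lower adjusted over the list alone (camera adjusted p = 0.0503 and 0.102), IDO1 (1.76 ± 0.53) and IL1B (-1.55 ± 0.38) among them. No member passed over the list alone, and camera made no call, for the unfolded protein response (median 0.20), amplified (0.30), Wnt (0.21), B and plasma cell (0.26), enteroendocrine (0.22), ribosomal (0.05), endothelial (-0.10), smooth muscle (-0.04) and mast cell lists (-0.13), with camera adjusted p between 0.0748 and 0.936. The erythrocyte median was 0.11. The mean of the columnar transcription factor list was 0.15, opposite to its median, and the Wnt (mean 0.02) and ribosomal lists (0.03) had medians above 0 with a camera direction of down.

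Without normal array 8, whose spread enters the common fit, 19 genes rose and 83 fell from Barrett's esophagus to adenocarcinoma. Without adenocarcinoma array 5, 71 rose and 168 fell, and without both, 187 rose and 361 fell, 81 and 274 of them by 2-fold or more. Adenocarcinoma array 5 and normal array 8 had been picked out by their squamous transcripts, so the values of squamous genes without them depend on that choice. With both arrays left out, the difference was -6.72 ± 0.77 for KRT4 and -7.61 ± 0.79 for RHCG, 14 of 14 epidermal differentiation complex genes, 8 of 9 squamous keratins and 16 of 17 cornified envelope genes fell over all genes, and these lists had adjusted p = 0.00707 each with an estimated correlation. COL10A1, MMP11, IDO1, the cystatins CST1 (2.80 ± 0.67) and CST4 (2.04 ± 0.45), and SNX10 (2.33 ± 0.43) then rose, as did 7 of 33 mitosis and 8 of 27 DNA replication genes. CST1, CST4 and SNX10 came from applying the naming rule to this smaller set. The count over all genes was 15 without adenocarcinoma array 4, 2 without adenocarcinoma array 8 and 153 with array weights.

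The calls of the comparisons with normal epithelium overlapped, with 194 genes higher and 33 lower in both Barrett's esophagus and adenocarcinoma, TFF1, AGR2 and LGALS4 among the higher. Independent lists of these sizes would share 28.8 and 3.61 genes. Simulated unchanged classes with a control class in common shared 0. That count cannot be set against the overlap, because genes rarely pass where none change. With the normal arrays split into separate controls, 45.4 and 1.59 genes were shared on average over 70 splits, each division used in both orders. Each comparison then had fewer normal arrays, so these counts cannot be set directly against those from all normal arrays. Across genes, the differences correlated at r = 0.781, with r = 0.506 for simulated unchanged classes and r = 0.579 on average with separate controls. The covariance was 0.422, against a simulated 0.0703 and 0.350 with separate controls. Since no gene passed between Barrett's esophagus and adenocarcinoma, none could pass in both steps, from normal epithelium to Barrett's esophagus and on to adenocarcinoma, and 119 did so in 1 direction without normal array 8 and adenocarcinoma array 5.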

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

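The tests on normal array 8 and on the likeness of normal array 5 and adenocarcinoma array 5 were chosen after these arrays had been seen, while the test of RNA integrity on the squamous lists was written down before its fit was run but after the ratio and the squamous scores of each array had been seen. Each list score and each of the 4 array quality measures was checked for 1 array far from the other 7 of its class by the gap to the nearest array divided by the range of the class. Of 108 groups of 8 arrays (32 lists and 4 measures in 3 classes) 17 stood out, all of them list scores, where chance gives about 1 in 20. The groups reuse the same arrays and are not independent, so these are not 17 separate events. Most came from normal arrays 8 and 5. Normal array 8 was the lowest of its class for the epidermal differentiation complex (0.855), squamous keratins (0.819), cornified envelope (0.824), desmosome (0.839), kallikreins and squamous serpins (0.854), basal layer (0.737), simple epithelial (0.716), columnar transcription factor (0.649), mitosis (0.847), DNA replication (0.673), retinoid metabolism (0.657) and xenobiotic metabolism lists (0.693). Normal array 5 was the highest of its class for the intestinal (0.615), gastric (0.732), matrix protease (0.677) and chemokine lists (0.644). Adenocarcinoma array 5 was the highest of its class for the basal layer list (0.605).

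Normal array 8 had low intensities of squamous transcripts. Low RNA integrity is argued against by its ACTB 3' over 5' log2 ratio of 0.0769, below the median of 0.309 of the other normal arrays. Its GAPDH ratio of -0.146 was less clear, above most of the other normal arrays but within their range (-0.379 to -0.108). Smooth muscle tissue in the specimen stays open as a candidate explanation, because this array was the highest of the normal arrays at 13 of 14 smooth muscle genes, fixed as a list beforehand. A specimen of another class under this label stays open too, since the mean correlation was 0.602 with normal, 0.641 with Barrett's and 0.665 with adenocarcinoma arrays, closest to adenocarcinoma array 6 (0.824), itself with a DES intensity of 12434. Its simple epithelial score of -3.96 (lowest of the 16 arrays of those classes -0.602, SD 0.665) decides nothing, as it lay below the other 7 normal arrays too and no other array had as high a smooth muscle score. The 4 other arrays with a smooth muscle score over 2 had simple epithelial scores of 0.786 (Barrett's array 2), 0.171 (normal array 5), 0.161 and -0.584 (adenocarcinoma arrays 5 and 6). No biological explanation was tested.

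Normal array 5 and adenocarcinoma array 5 were the most alike pair. The SD of their log2 difference over all tested genes was 0.399, against 0.486 for the next pair and a median of 0.942 for pairs within a class. One specimen or RNA on both arrays cannot be told apart from similar tissue in both specimens, as no value shows how alike repeat arrays of 1 RNA would be. Whatever the shared number stands for stays open too, a reading reached after the values below had been seen. The deviations of the other 7 same-numbered normal and adenocarcinoma pairs had a mean correlation of -0.0306 (SE 0.0339). Same-numbered pairs with Barrett's arrays had means of 0.119 and 0.103, with number 5 included. Barrett's array 5 was close to both arrays (r = 0.904 and 0.910 across genes). Normal array 6, with another number, was at least as close to them (r = 0.907 and 0.915).

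Squamous transcripts were lower in adenocarcinoma, where the 3' over 5' ratio was higher. With the ratio as a covariate, the median difference of the 40 genes of the epidermal differentiation complex, squamous keratin and cornified envelope lists from normal epithelium went from -3.81 (median SE 1.06) to -2.71 (median SE 1.29), and the number of them that passed went from 37 to 0. The calls ended because the difference shrank and the standard error grew. RNA integrity as the whole cause is argued against by the size of what was left and by adenocarcinoma arrays 6 and 8, whose mean ratios were 0.0892 and 0.0947 and whose squamous scores were -3.58 and -3.58. A part played by RNA integrity stays open, and so does the tissue class itself.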

How the results depend on the processing

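The counts of 246, 2084 and 0 genes (Barrett's minus normal, adenocarcinoma minus normal, adenocarcinoma minus Barrett's) were within 1.5 times under a pseudocount of 1, a floor of 64, quantile normalization, a median shift, no filter, a 60th percentile filter, the median of probe sets, a random block, only 2 classes and a robust trend. With all probe sets, adenocarcinoma minus normal gave 3278, and without the suffix _x_at or _s_at the counts were 134 and 1220 for the comparisons with normal epithelium, since more and fewer features were tested. The rank test gave 953 for adenocarcinoma minus normal. The sample number as a fixed block gave 11 for adenocarcinoma minus Barrett's, and array weights gave 1197 for Barrett's minus normal, 153 for adenocarcinoma minus Barrett's and 13 genes changed in both steps; the cause was not tested. Whether the numbers pair arrays stayed open. Deviations from the class mean matched best within the own number for 2 (Barrett's and normal), 0 (adenocarcinoma and normal) and 3 (adenocarcinoma and Barrett's) of 8 numbers. Their mean r was 0.119, -0.00822 and 0.103 for the same number and -0.0150, -0.000241 and -0.0141 for different numbers, with 4, 1 and 3 of 8 over 0.1. With an estimated correlation, 0, 0 and 0 of 16, 25 and 15 lists were called by camera. The planned fry test passed some of these lists and not others. In Barrett's minus normal, fry adjusted p was 0.00147 (intestinal) and 0.000578 (gastric), but 0.276 (mitosis) and 0.347 (collagens). For squamous keratins it was 0.00318 in adenocarcinoma minus normal. In adenocarcinoma minus Barrett's it was 0.0144 for squamous keratins and for DNA replication, but 0.195 for mitosis and 0.398 for collagens.

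Leaving out each array gave 143 to 548, 1667 to 2791 and 0 to 239 genes, 0 to 9 in both steps, and 14 to 17, 20 to 26 and 14 to 20 lists. The list cytosolic ribosomal proteins, adenocarcinoma minus Barrett's, had an adjusted p of 0.0412 to 0.978 and turned from down to up without Barrett's array 6 (0.0412). The following were chosen after seeing the data, the arrays left out because of their squamous and columnar transcripts, so their squamous and columnar values are not independent of that choice. Without normal array 8 and adenocarcinoma array 5 the counts were 756, 3202 and 548, with 119 in both steps, and the 246 genes and 2056 of the 2084 were among them. The desmosome list turned down in Barrett's minus normal (adjusted p = 0.0432). Without normal array 5 as well, they were 883, 3127, 528 and 117. With the 3' over 5' ratio as a covariate, Barrett's minus normal gave 202, of which 194 were among the 246, and adenocarcinoma minus normal gave 80. Smooth muscle turned up against normal epithelium (adjusted p = 0.463) and Barrett's esophagus (0.00803), and T and NK cells turned down in adenocarcinoma minus Barrett's (0.956); the cause was not tested. Of the named genes, none that passed in the main fit or in an alternative reversed direction under that alternative. Changes of sign in genes that passed in neither were not counted as reversals.

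Of 100 drawn splits of the same 16 arrays, the real one included, 2 gave as many genes as Barrett's minus normal (246, highest other 250) and 1 as many as adenocarcinoma minus normal (2084, highest other 1061), so the share was under 0.05 for both. That share makes a random division of the arrays an unlikely source of these counts but does not exclude it. For Barrett's minus normal another split gave more genes than the real one. For adenocarcinoma minus Barrett's the real count was 0, which every one of the 100 splits meets (highest other 3), so the splits say nothing about chance. Signal over background limits the dim genes, for which no background value was used here.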

Other observations

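Barrett's arrays 4 and 5 held little of the intestinal program or of the other main columnar lists. Their gastric (-0.951 and -0.612), simple epithelial (-0.440 and -0.602) and columnar transcription factor scores (-0.453 and -0.741) were the lowest of the class. Their squamous keratin scores, 1.95 and 2.30, lay within the range of the normal arrays other than array 8. Their OLFM4 intensities were 8.5 and 1.4, against 549.8 to 10038 on the other 6 Barrett's arrays, and their LGALS4 intensities were 495.4 and 857.6, against 8169.5 to 20581. The same arrays had the highest MMP1 intensities of the class, 10448 and 10835, against 249.8 to 700.6.

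The first 3 principal components of the 24 arrays held 33.5%, 14.1% and 10.0% of the variance. Within a class, the mean correlation between arrays across genes, which are not independent replicates, was 0.816 in normal epithelium, 0.855 in Barrett's esophagus and 0.803 in adenocarcinoma.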
